A study of Drosophila melanogaster with 12 samples.

How the data were processed

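RNA was measured in whole adult flies of Drosophila melanogaster by sequencing of polyA-selected libraries. Per the labels' protocols, flies were frozen in liquid nitrogen, RNA was extracted with Trizol and cleaned on Qiagen columns, and libraries were made with the Illumina TruSeq Standard mRNA kit. The 12 libraries fall into 4 groups of 3: wildtype, flies labelled heterozygous for an AKHR mutation with no obese parent (het), and flies of the same labelled genotype with an obese father (paternal) or an obese mother (maternal). Sex is not given in the sources used here. Whether each library came from a separate culture is stated only as far as 1 set of samples per experimental replicate, so p-values measure the spread between these libraries.

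The authors deposited 5 tables of genes, each comparing a pair of groups. Per the file headers, coordinates are on the D_melanogaster_Apr_2006 assembly, and the submitters' processing notes name dm3, Novoalign and DESeq. Their versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Per the file headers, the deposited columns hold read counts per gene, FPKM values, log2 fold changes and adjusted p-values. The exon columns hold a log2 ratio and an adjusted p, read as those of the exon of a gene with the most altered usage. They list an exon for only 71 to 99 genes per table, and the lowest absolute log2 ratio listed was 1. The deposited adjusted p-values are written as a score. That score was compared with minus 10 times the log10 of adjusted p from a DESeq2 run on the 6 libraries of each table. The median ratio of the deposited score to that value was 1 in Pat vs WT, Mat vs WT, Pat vs Het and Mat vs Het with independent filtering. In Het vs WT it was 0.859 with filtering, where 143 genes passed on each side but only 96 were shared, and 1 without filtering, where all 143 were shared. The score was therefore read as minus 10 times log10, and which filter setting the authors used was not determined. The same scale was assumed for the exon scores, where it was not tested. The deposited FPKM values were used to work out total reads and as an alternative measure of AkhR.

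Counts and FPKM of a library present in several tables were identical in all of them, with 0 disagreements. Joining the tables gave 13040 genes, of which 12982 had counts in all 12 libraries and 58 were left out. Depth was 17212029 to 21370713 listed reads per library, 99.985 to 99.986% of the totals that the FPKM values imply. Gene symbols are those of the files. A table of current names matched 12527 of the gene IDs, and 2707 of those had another current symbol. AkhR is listed in the tables as GRHR (FBgn0025595). Start positions were converted to count from 1. Of the genes, 5309 overlapped another listed gene, 246 shared an exact interval with another and 198 had the same counts as another gene on the same chromosome.

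Gene changes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12809. Library sizes were scaled by TMM, and a robust quasi-likelihood fit used all 12 libraries with group means. The 6 contrasts were Het vs WT, Pat vs WT, Mat vs WT, Pat vs Het, Mat vs Het and Mat vs Pat, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Changes are log2 values with the standard error of the fit. The biological coefficient of variation was 0.0591. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the 34 lists. Shares of genes by chromosome carry exact binomial intervals at the 95% level, which cover counting error only.

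Group assignments, tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, AkhR was always named, with up to 6 genes of largest rise and 6 of largest fall among those past the threshold with a mean of at least 1 CPM and no overlap between the 3 libraries of each group. Up to 4 members past the threshold were named from each of up to 6 lists. Where fewer than 6 genes passed, the 6 with the smallest p were named. Chromosome regions, the distance from AkhR, the exon results and list members that did not pass were chosen after their values were seen.

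Replicate numbers 1 to 3 recur in each group, and the series design describes 1 set of samples per experimental replicate; that a number marks such a set was read from the titles. Deviations from group means correlated at a mean r across genes of 0.119 between libraries of the same number and -0.0592 between libraries of different numbers. Of 18 pairs with the same number, 11 were above 0.1, with a range from -0.0273 to 0.221, and 11 of 12 libraries correlated best with their own number. Every pair was above 0.1 in Pat vs Het (from 0.133) and Mat vs Het (from 0.16), but not in the other 4 comparisons. On the design text the numbers were taken to pair the libraries. The edgeR fit fixed beforehand left this pairing out, and results below come from it unless another setting is named. With the block 284, 206 and 227 genes passed in Het, Pat and Mat vs WT, against 76, 67 and 44 without it. Values from a fit with the replicate number as a block are given where they change the call of a named gene or a list. They are also given where they move the count of genes or lists of a comparison by over 1.5 times, and for some list members.

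Alternatives were DESeq2 1.42.0, limma-trend, DESeq2 size factors, deposited FPKM for AkhR, no scaling factors, no filter, a filter of 1 CPM in at least 6 libraries, only the 6 libraries compared, no robust fitting, a 2-fold minimum, the replicate block, an estimated correlation and fry for lists, and each library left out in turn. Leaving out libraries in the list tests was added after the data were seen. The test was tried on simulated counts for Het vs WT with 12776 genes. The changed genes were drawn from those with a mean of at least 1 CPM. Counts were drawn independently, with no effect of replicate set. Of 50 such genes changed by each fold the test recovered 16 at 1.2-fold, 47 at 1.5-fold, 47 at 2-fold and 50 at 4-fold, with 6 false calls among 166. Unchanged groups against shared controls were simulated 50 times, with all 12 libraries, controls included, drawn independently around the mean of all 12. No pair of libraries of a group agreed within sampling noise, with chi-square per degree of freedom from 3.59 to 12.5.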

Results

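Transcript levels were measured in whole flies of the Canton S background aged 10 to 11 days. AkhR encodes the receptor for adipokinetic hormone, a peptide that mobilises stored fat and glycogen in insects. The design sets wildtype flies beside 3 groups labelled heterozygous for an AKHR mutation, which differ in whether neither parent, the father or the mother was obese. Each group held 3 libraries of 17212029 to 21370713 listed reads, and 12809 genes were tested. Maternal replicate 1 stood apart from the rest: cytosolic ribosomal protein genes took 6.383% of its reads, against 5.475 to 5.852% in the other 11 libraries.

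The targeted gene was examined first. AkhR (listed as GRHR, FBgn0025595) lies on chromosome 2L from 6711286 to 6716186 on the minus strand of dm3. Its level was 82.3 ± 4.33 CPM (SD, n = 3) in wildtype, 79.0 ± 6.59 in het, 78.4 ± 4.08 in paternal and 79.8 ± 4.52 in maternal flies. The log2 change was -0.06 (SE 0.0648) in Het vs WT, -0.07 (SE 0.0647) in Pat vs WT and -0.04 (SE 0.0648) in Mat vs WT, with edgeR adjusted p of 0.804, 0.773 and 0.810. The 95% interval in Het vs WT ran from -0.19 to 0.08, so a log2 fall of 1 lay outside it. The kind of mutation is not given in the labels, and a transcript count over the whole gene therefore does not check them.

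**Figure D1:**
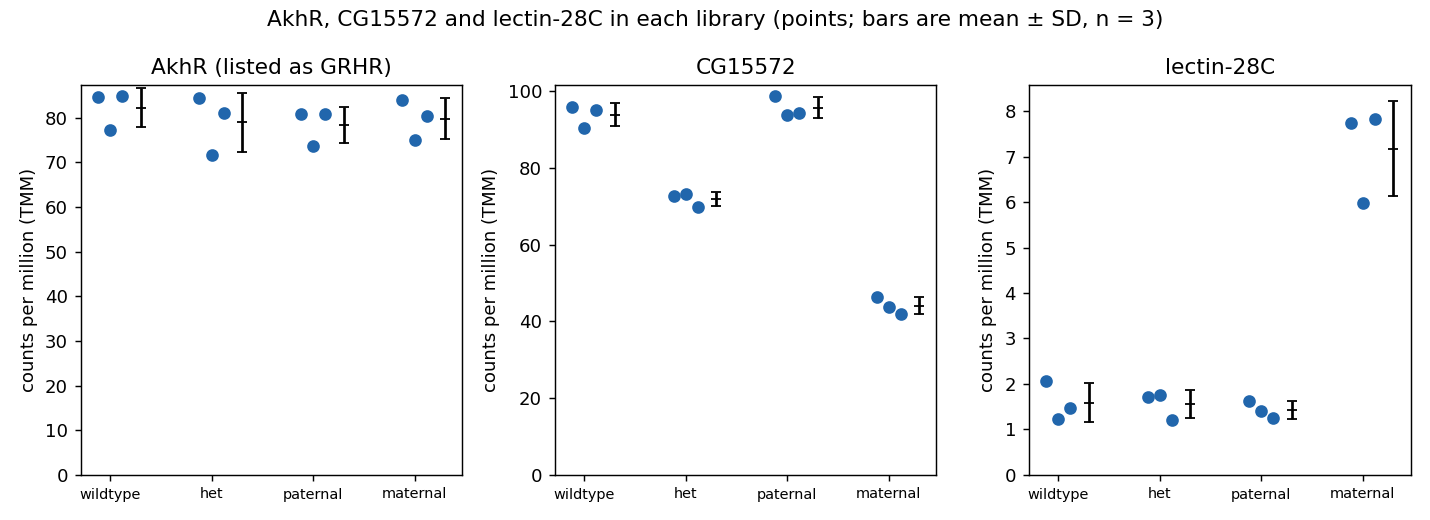
TMM-scaled CPM of AkhR, CG15572 and lectin-28C (y axes, starting at 0) in the 4 groups (x axis). Points are libraries and bars beside them the mean ± SD of 3 libraries; AkhR levels overlap in all groups, CG15572 is 44.0 CPM in maternal flies against 95.7 in paternal flies, and lectin-28C is 7.18 CPM in maternal flies against 1.43 to 1.59 in the others.

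To explore what accompanied the labelled genotype without parental obesity, het flies were compared with wildtype. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 26 genes rose and 50 fell, 76 in all. The changes gathered on chromosome arm 2L, which bears AkhR: 53 of the 76 were on this arm, which holds 19.2% of tested genes. CR43263 (2L, 1216854 to 1217785) had 1 read in total in the 3 wildtype libraries and 504 in the 3 het libraries, a ratio of 518 after depth with a 95% counting interval from 92.6 to 20500. CG9505 (2L, 6367884 to 6370195) rose by a log2 of 1.66 (SE 0.119, adjusted p = 1.19e-07), and CG15818 (2L, 7410909 to 7412229) fell by 1.29 (SE 0.0989, adjusted p = 3.57e-07).

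The other large rises in het flies were CR43821, CG14945, CG42751 and CG42329, at log2 changes of 4.10, 1.22, 1.03 and 0.87. CR43821 overlaps Syt1, CG14945 overlaps JhI-21 and CG42751 overlaps Pde1c, so their reads may be shared. The other large falls were CG9486, CG43401, CG3528, CR43142 and CG43402, at -1.19, -1.08, -0.83, -0.75 and -0.72, and CG9486 overlaps Ddr. All of these lie on 2L. Off 2L, 22 of the 23 called genes fell, with a median log2 change of -0.32. With the replicate block 284 genes passed, 113 higher and 171 lower, and 141 of them (49.6%) lay on 2L, a smaller share than without the block. The direction of the calls off 2L was not counted with the block or without scaling factors. Without scaling factors 67 passed, 32 higher and 35 lower. The count was 41 without het replicate 1 and 45 without wildtype replicate 2. Of the 21 named genes past the threshold, 12 passed whichever library was left out. CG14945 did not pass with only the 6 libraries compared (adjusted p = 0.120).

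**Figure D2:**
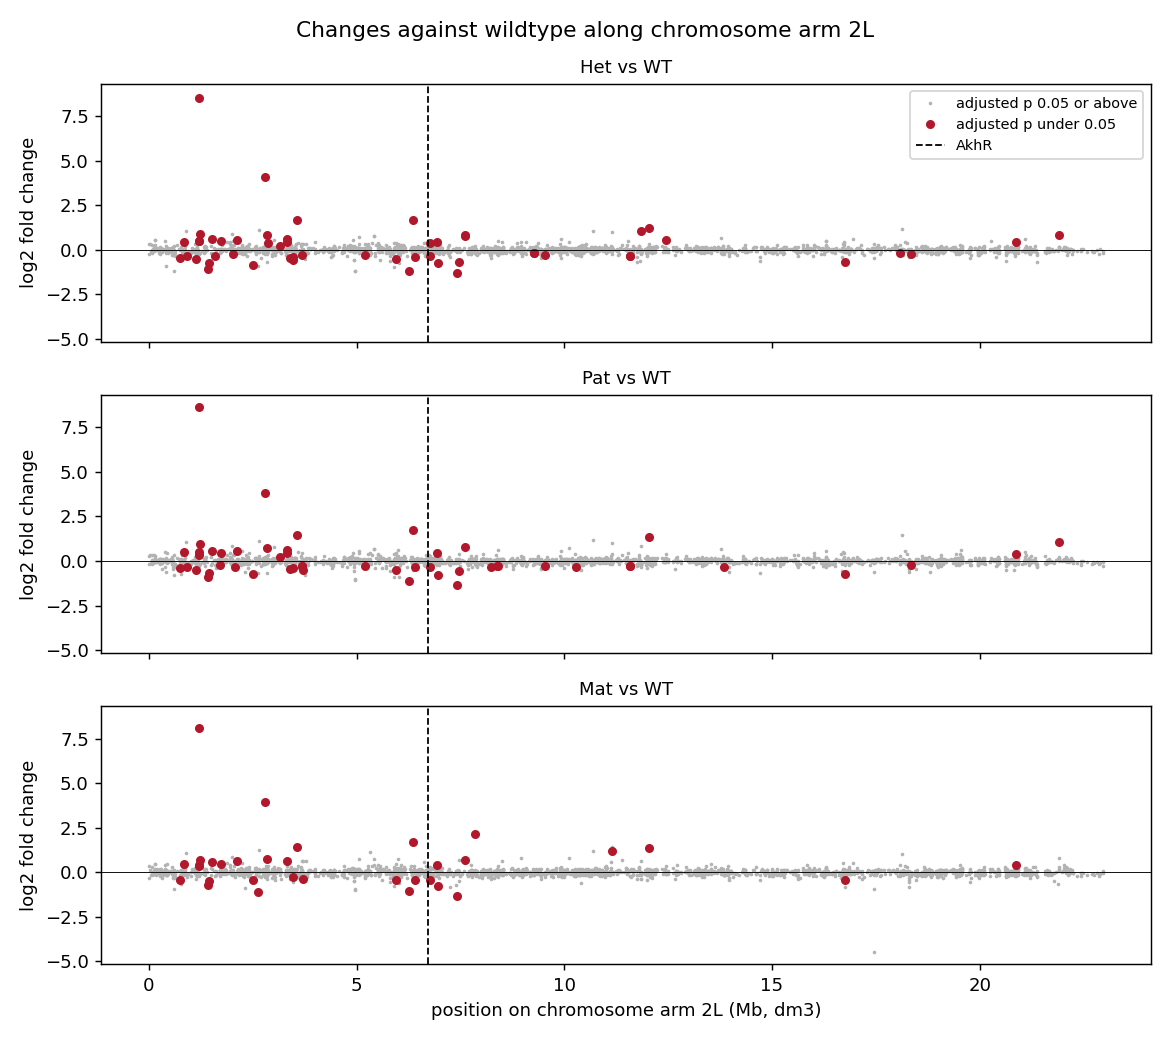
Log2 fold changes against wildtype (y axis) of genes on chromosome arm 2L by position in Mb on dm3 (x axis), with 1 panel for each labelled heterozygous group. Red points passed an adjusted p of 0.05, grey points did not and the dashed line marks AkhR; within 7.5 Mb of AkhR, a boundary chosen after the calls were seen, lay 1727 of the 2454 tested 2L genes and 48 of the 53 called in Het vs WT, 47 of 51 in Pat vs WT and 31 of 33 in Mat vs WT.

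Gene lists fixed beforehand were tested next. Genes of the male accessory gland, whose products are transferred in seminal fluid, had a median log2 change of -0.16 in Het vs WT. Of 24 members 1 fell in edgeR, Acp36DE (-0.21, SE 0.048, adjusted p = 0.0433), 5 passed in DESeq2 and 2 in limma-trend, and 12 fell when adjusted over the list alone. The camera adjusted p was 2.53e-11 at the preset correlation, while adjusted p = 0.896 with an estimated correlation. Of 17 photoreceptor genes 2 fell, the opsin Rh3 (-0.29, SE 0.0597, adjusted p = 0.0222) and the arrestin Arr1 (-0.20, SE 0.0433, adjusted p = 0.0415), and 5 fell when adjusted over the list alone. Of 12 Bomanins and immune-induced peptides, which are secreted in the response to infection, CG15068 and CG5778 fell by 0.41 and 0.32 on the log2 scale. The digestive protease Ser8 fell by 0.57 among 22 listed proteases, 5 of which fell when adjusted over the list alone. Among 26 cytochrome P450 genes Cyp4d21 rose by 0.77 and Cyp28d1 fell by 0.26, both on 2L. The cuticle gene Cpr47Ef fell by 0.39 among 38. Acp36DE and Arr1 also lie on 2L, while Rh3, CG5778, CG15068, Ser8 and Cpr47Ef lie on other arms. With the replicate block 5 accessory gland, 5 photoreceptor, 3 protease and 2 cuticle genes passed in Het vs WT. Of these genes CG5778, Cyp28d1, Ser8 and Acp36DE overlap another gene (CG5791, CG7742, CG42321 and Fas3), so their reads may be shared.

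The 8 lists past the threshold in Het vs WT were the accessory gland, photoreceptor, Bomanin, protease, muscle, neuronal and cytosolic ribosomal protein lists, which were lower, and the testis and sperm list, which was higher at a median of 0.08. Of its 25 members 0 passed in edgeR, DESeq2 or limma-trend, and 7 had an unadjusted p under 0.05. None of the 8 held with an estimated correlation, where the adjusted p was 0.896 or 0.957. The Bomanin call ended without wildtype replicate 3 (adjusted p = 0.0716), the muscle call without wildtype replicate 3 (0.224) or het replicate 1 (0.137), the neuronal call without het replicate 1 (0.0515) and the cytosolic ribosomal call without wildtype replicate 2 (0.288) or het replicate 3 (0.332). The calls of Acp36DE, Arr1 and CG15068 ended whichever library was left out, with adjusted p up to 0.317, 0.262 and 0.205. The call of Cyp28d1 held only without het replicate 2 and that of Rh3 only without wildtype replicate 1, with adjusted p up to 0.317 and 0.155 otherwise. Het replicate 1 was among the libraries without which the calls of CG42751, Cpr47Ef, CG5778 and Ser8 ended, with adjusted p up to 0.132, 0.106, 0.0749 and 0.0769; CG42751 also needed wildtype replicates 2 and 3 and het replicate 2, Cpr47Ef wildtype replicate 1 and het replicate 2, CG5778 wildtype replicate 1 and Ser8 het replicate 3.

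The lists for AKH signalling, fatty acid synthesis and beta-oxidation had 0 members past the threshold in each of the 6 comparisons with edgeR, with or without the replicate block, DESeq2 and limma-trend. For AKH signalling and fat mobilisation, 11 genes had a median log2 change of 0.01 in Het vs WT, and the number at an unadjusted p under 0.05 was 0 in Het vs WT, 0 in Pat vs WT, 3 in Mat vs WT and 1 in each of the other 3 comparisons. For fatty acid and triglyceride synthesis the median in Het vs WT was -0.05 over 16 genes, 2 of which had an unadjusted p under 0.05, and for fatty acid beta-oxidation it was -0.01 over 18 genes, 0 of which did. The last of these was 0.01 without scaling factors. The beta-oxidation list had medians of 0.03 in Mat vs Het and 0.04 in Mat vs Pat, with camera adjusted p of 0.0715 and 0.0511, and passed with the replicate block (0.0437 and 0.0401), while adjusted p = 0.775 and 0.844 with an estimated correlation. In the glycolysis list Gpdh rose by 0.38, 0.43 and 0.45 in Het, Pat and Mat vs WT. Its edgeR adjusted p was 0.205, 0.171 and 0.147, and 0.00033, 8.7e-05 and 7.4e-05 with the replicate block. DESeq2 called 1 of the 14 glycolysis genes in each of these. The storage protein gene Lsp1alpha rose by 0.39, 0.33 and 0.35, passing in edgeR only with the block (0.0145, 0.0435 and 0.0344). The starch digestion gene Amy-d fell by 0.18 in Het vs WT (0.0143 with the block).

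Flies with an obese father were next compared with wildtype. In Pat vs WT 20 genes rose and 47 fell, 67 in all, and 51 of them lay on 2L. CR43263 had 565 reads against 1 in wildtype, a ratio of 572 with a 95% counting interval from 102 to 22600. CG9505 rose by 1.76 (SE 0.118, adjusted p = 3.80e-08) and CG15818 fell by 1.33 (SE 0.0991, adjusted p = 2.24e-07). CR43821, CG14945, CG11629 and CG42329 rose by 3.83, 1.37, 1.06 and 0.96, and CG9486, CG43401, CR43142, CG3528 and yellow-b fell by 1.12, 0.90, 0.79, 0.76 and 0.72 on the log2 scale. Yellow-b overlaps CG13278. All 16 called genes off 2L fell, a direction not counted with the replicate block or without scaling factors. Of these 67, 53 had also been called in the same direction in Het vs WT.

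In paternal flies 3 of 24 accessory gland genes fell, Acp29AB, Acp36DE and Mst57Dc, at log2 changes of -0.30, -0.22 and -0.26, while 4 passed in DESeq2, 3 in limma-trend and 6 with the replicate block, and 14 fell when adjusted over the list alone. The list had a median of -0.17 and a camera adjusted p of 4.18e-14, with adjusted p = 0.658 with an estimated correlation. Cyp4d21 rose by 0.78, and Cyp28d1, Cpr47Ef and Ser8 fell by 0.28, 0.37 and 0.49. Of the list members named here, Acp29AB, Acp36DE, Cyp4d21 and Cyp28d1 lie on 2L, and Mst57Dc, Cpr47Ef and Ser8 on other arms. Antimicrobial peptide genes had a median of -0.40 over 18 genes and the 11 mitochondrially encoded genes one of -0.35, with camera adjusted p of 0.00521 for each, 0.715 and 0.658 with an estimated correlation. In each list 0 members passed in edgeR, DESeq2 or limma-trend, and 1 had an unadjusted p under 0.05; with the replicate block the mitochondrial gene mt:CoII passed (-0.20, adjusted p = 0.0390). The antimicrobial median was -0.80 without wildtype replicate 2 and -0.69 without paternal replicate 1. The antimicrobial call ended without wildtype replicate 3 (median -0.01, adjusted p = 0.758) or paternal replicate 3 (-0.25, 0.210) and the mitochondrial call without wildtype replicate 1 (-0.21, 0.0552) or paternal replicate 3 (0.0658). In all 13 lists passed, and with an estimated correlation 0 did.

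With the replicate block 206 genes passed in Pat vs WT, 113 of them (54.9%) on 2L. Without scaling factors 54 passed, 22 higher and 32 lower. The count was 41, 34 and 39 without wildtype replicates 1, 2 and 3, 33 without paternal replicate 1 and 36 without paternal replicate 3, and 7 lists passed without paternal replicate 3. The call held for 12 of the 19 named genes whichever library was left out, and ended for Acp36DE and Cyp28d1 in every case, with adjusted p up to 0.305 and 0.302. The calls of Mst57Dc and Acp29AB held only without wildtype replicate 1 and that of Ser8 only without wildtype replicate 3, with adjusted p up to 0.236, 0.302 and 0.185 otherwise. The call ended for Cpr47Ef without wildtype replicates 1 or 2 or paternal replicates 1 or 3, with adjusted p up to 0.168, and for Cyp4d21 without wildtype replicate 2, at an adjusted p of 0.052. CG14945 and Ser8 did not pass with only the 6 libraries compared (adjusted p = 0.0728 and 0.0736).

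Flies with an obese mother were compared with wildtype in the same way. In Mat vs WT 20 genes rose and 24 fell, 44 in all, with 33 on 2L and 3 on the X. CR43263 had 362 reads against 1, a ratio of 382 with a 95% counting interval from 68.2 to 15100. Lectin-28C (2L, 7857077 to 7858136), named as a C-type lectin, rose by 2.16 (SE 0.178, adjusted p = 5.45e-07), and CG15572 (X, 4162734 to 4165116) fell by 1.09 on the log2 scale (SE 0.0524, adjusted p = 9.16e-11). CR43821, CG9505 and CG14945 rose by 3.94, 1.67 and 1.36, CG31867 rose from 0.817 ± 0.0973 to 1.89 ± 0.195 CPM (SD, n = 3), and CG15818, CG43403, CG9486, CR43494 and CR43142 fell by 1.37, 1.10, 1.08, 1.02 and 0.76. CG31867 overlaps Gyc32E and CR43494 overlaps kirre. Among list members CG5778 fell by 0.29 and Cyp4d21 rose by 0.68.

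The accessory gland list had a median of -0.13 in Mat vs WT, with a camera adjusted p of 5.17e-07, but adjusted p = 0.603 with an estimated correlation. It was -0.06 (adjusted p = 0.0471) without maternal replicate 3 and -0.08 without wildtype replicate 2. Of its 24 members 5 passed adjusted over the list alone. The testis and sperm list had a median of 0.11 and an adjusted p of 5.41e-08, but adjusted p = 0.603 with an estimated correlation, with 4 of 25 members past the threshold adjusted over the list alone. Its median was 0.07 without maternal replicate 1 and 0.17 without maternal replicate 3. The 5 Turandot stress peptides had a median of 0.65, which was 0.34 without maternal replicate 1, the library with the highest ribosomal protein share, and the maternal libraries stood at 0.83, 0.27 and -0.23. The Turandot camera adjusted p was 0.000566, but adjusted p = 0.603 with an estimated correlation. Over all genes 0 members of these 3 lists passed in edgeR and limma-trend and 1 of each in DESeq2, with 3, 3 and 0 under the replicate block, while 10, 10 and 1 had an unadjusted p under 0.05. In all 11 lists passed, and 0 with an estimated correlation. With the replicate block 227 genes passed, 102 of them (44.9%) on 2L. The count was 27 without wildtype replicate 1 and 116 without maternal replicate 3. The call of Cyp4d21 ended without each of the 3 wildtype libraries, and that of CG5778 without these or maternal replicate 2, with adjusted p up to 0.137 and 0.152. CG31867 kept its call only without maternal replicate 1, and CG43403 only without that library or wildtype replicate 3, with adjusted p up to 0.160 and 0.191 otherwise.

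Against the same wildtype libraries, 32 genes were called in the same direction in all 3 comparisons, 17 higher and 15 lower, and 29 of them lay on 2L. With the replicate block there were 104. Fold changes correlated across genes, which are not independent replicates, at r = 0.769 for Het vs WT and Pat vs WT, where simulated unchanged groups gave 0.503. The covariance was 0.0242 against a simulated 0.00966. These 2 comparisons shared 20 genes higher and 33 lower, 53 in all. Simulated unchanged groups with a shared simulated control shared a mean of 0.06 and at most 1. The controls were simulated too, so an offset of the actual wildtype libraries is absent from these simulated values. Independent lists would share 0.0406 higher and 0.183 lower. The correlation was 0.723 for Het vs WT and Mat vs WT and 0.744 for Pat vs WT and Mat vs WT, against 0.495 and 0.501 simulated, and their covariances exceeded the simulated ones by 0.0138 and 0.0149. The 3 wildtype libraries cannot be split so that each part keeps 2, so part of the excess may come from the shared controls.

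**Figure D3:**
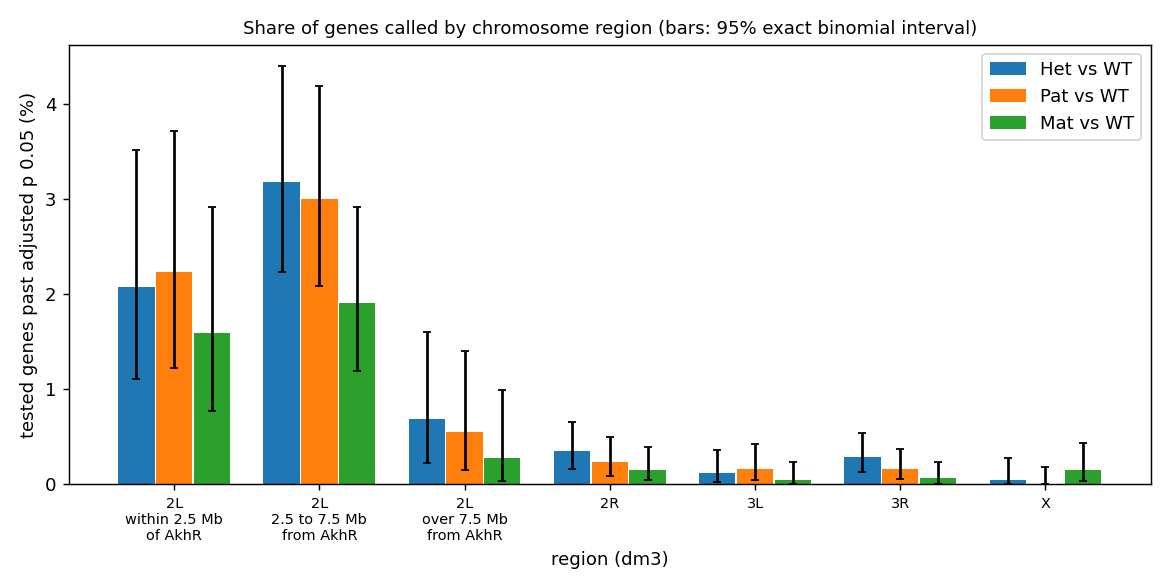
Percent of tested genes past an adjusted p of 0.05 (y axis) by chromosome region on dm3 (x axis) in the 3 comparisons with wildtype. Bars carry 95% exact binomial intervals, and in Het vs WT the share is 2.07% within 2.5 Mb of AkhR on 2L, 3.18% at 2.5 to 7.5 Mb, 0.688% farther along 2L and 0.0501% on the X.

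Groups of the same labelled genotype that differ in the obese parent were compared next; the direction of the cross may differ with the parent, so these comparisons do not separate them. In Pat vs Het 1 gene passed, CG15572, which rose by 0.41 (SE 0.0506, adjusted p = 0.00167). In Mat vs Het 2 genes passed: lectin-28C rose by 2.19 (SE 0.179, adjusted p = 1.23e-06) and CG15572 fell by 0.71 (SE 0.0529, adjusted p = 4.79e-07). CG15572 stood at 93.9 ± 2.96 CPM in wildtype, 72.0 ± 1.84 in het, 95.7 ± 2.70 in paternal and 44.0 ± 2.20 in maternal flies (SD, n = 3). Lectin-28C stood at 1.59 ± 0.420, 1.56 ± 0.305, 1.43 ± 0.192 and 7.18 ± 1.05 CPM, and had 120 to 137 reads in each maternal library. It overlaps TwdlE, which had 3 to 13 reads per library. These calls held whichever library was left out, with adjusted p up to 0.0331 for CG15572 in Pat vs Het. At an unadjusted p under 0.05 there were 270 genes in Pat vs Het and 532 in Mat vs Het. Both are below a share of 0.05 of the 12809 genes tested, which is the share expected with no change. In Pat vs Het 2 genes passed without het replicate 3.

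The next genes by p did not pass. In Pat vs Het they were CR43381, CG8866, CG43679, Cpr67Fb and CG17807, each with an adjusted p of 1. In Mat vs Het they were CG16756 (0.27, adjusted p = 0.712), CG31867 (1.07, 0.712), CG3528 (0.38, 0.712) and the ribosomal protein gene RpS14a (0.19, 0.755). Fold changes of Pat vs Het and Mat vs Het correlated across genes at r = 0.481, where simulated unchanged groups gave 0.5, and the covariance was 0.00777 against 0.00966. The comparisons shared 0 calls in the same direction and 1 in opposite directions, CG15572.

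By list, 3 passed in Pat vs Het: antimicrobial peptides at a median of -0.48 over 18 genes, mitochondrially encoded genes at -0.22 over 11 and glycolysis at 0.05 over 14, with camera adjusted p of 6.22e-06, 0.000689 and 0.0230 and adjusted p = 0.974 with an estimated correlation for each. In each list 0 members passed in edgeR, DESeq2 or limma-trend, and 1, 1 and 0 had an unadjusted p under 0.05. The antimicrobial list had library medians of 0.22, -0.14 and 0.51 log2 in het flies and 0.10, -0.16 and -0.61 in paternal flies. Its call ended without het replicate 3 (median -0.22, adjusted p = 0.0759), and its median was -0.26 without paternal replicate 3 and -0.77 without paternal replicate 1. The mitochondrial median was -0.35 without het replicate 1, and its call ended without het replicate 2 (-0.05, 0.394) or paternal replicate 3 (0.0918), and the glycolysis call without het replicates 1 or 2 or paternal replicate 3 (0.146, 0.109 and 0.416). Without paternal replicate 1, 7 lists passed. In Mat vs Het 5 lists passed. The 92 cytosolic ribosomal protein genes had a median of 0.06 (adjusted p = 1.62e-15) and the 72 mitochondrial ribosomal protein genes one of 0.05, beside nuclear oxidative phosphorylation, glycolysis and Turandot genes. Over all genes 0 members of the 5 lists passed in edgeR, DESeq2 or limma-trend, where 21 cytosolic and 6 mitochondrial ribosomal protein genes had an unadjusted p under 0.05; 4 cytosolic ribosomal protein genes passed adjusted over the list alone, and adjusted p = 0.775 with an estimated correlation for all 5. Without maternal replicate 1, whose ribosomal protein share was highest, the cytosolic ribosomal median was 0.01 with an adjusted p of 0.159, and none of the 5 passed. The glycolysis call also ended without het replicates 1 or 2 or maternal replicate 3 (0.117, 0.0944 and 0.625), and the Turandot call without het replicate 1 (0.285). Without het replicate 3, maternal replicate 2 or maternal replicate 3 there were 9, 12 and 10 lists, and with the replicate block 10 lists passed in Mat vs Het.

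**Figure D4:**
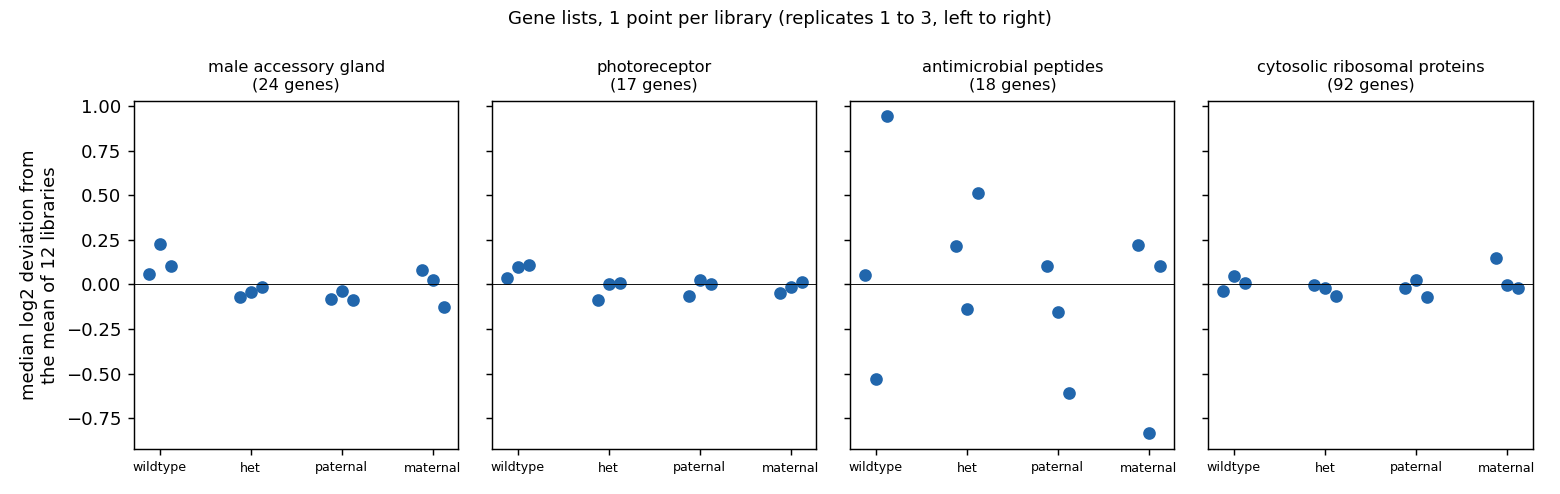
Median log2 deviation of the genes of 4 lists from their mean over the 12 libraries (y axis) in the 4 groups (x axis), with 1 point per library. Accessory gland genes lie above 0 in the 3 wildtype libraries and in maternal replicates 1 and 2, antimicrobial peptide genes range from -0.83 to 0.94, and cytosolic ribosomal protein genes are at 0.15 in maternal replicate 1.

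The groups with an obese mother and an obese father were compared directly, which tests whether their changes against het differ. In Mat vs Pat 2 genes passed, lectin-28C at 2.32 (SE 0.182, adjusted p = 5.73e-07) and CG15572 at -1.12 (SE 0.0524, adjusted p = 1.15e-10). With the replicate block 3 passed, the third being the mitochondrial gene mt:CoII at 0.35 (adjusted p = 0.00196, against 1.00 without the block), which was named after its values were seen. The next genes did not pass: CR43494, CR43263, CG14500 and CG8866, with adjusted p of 0.217, 0.384, 1.00 and 1.00. There were 352 genes at an unadjusted p under 0.05, below a share of 0.05 of the 12809 tested, the share expected with no change. By list 9 passed, and 0 did with an estimated correlation. Among the 9, cytosolic ribosomal proteins had a median of 0.06 (camera adjusted p = 2.18e-14, and 0.844 with an estimated correlation). Of the 92 genes of that list 0 passed in edgeR, DESeq2 or limma-trend, and 0 had an unadjusted p under 0.05. Without maternal replicate 1 none of the 9 passed, and the cytosolic ribosomal median was 0.01.

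The authors' deposited table for Het vs WT lists 143 genes past an adjusted p of 0.05, that for Pat vs WT 137 and that for Mat vs WT 48. These include 69, 63 and 34 of the genes called by edgeR. The authors' deposited table for Pat vs Het has 1 gene past the threshold and that for Mat vs Het 2, which edgeR also called. The authors' deposited tables also list exon usage. An exon of CG18284, on 2L from 10645160 to 10645315, had a log2 ratio of 2.61 in Mat vs WT and 2.89 in Mat vs Het, with deposited scores read as adjusted p of 1.08e-44 and 1.69e-40, on a scale tested for genes but not for exons. The gene-level log2 change of CG18284 in edgeR was 0.00 in Mat vs Het, at an adjusted p of 0.998. An exon of dpr3, on 2L from 2066742 to 2067160, had a ratio of 1.41, 1.40 and 1.40 against wildtype in the authors' deposited tables for het, paternal and maternal flies. The log2 change of the dpr3 gene as a whole in edgeR was -0.19, -0.34 and -0.27, with adjusted p of 0.205, 0.00769 and 0.0587, the last being 0.0123 for dpr3 with the replicate block.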

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

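The tests of chromosome position, of the share of rising genes and of the het midpoint were chosen after the results were seen.

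CG15572 was picked out because its change against het differed between the maternal and paternal groups, by -1.12 on the log2 scale in Mat vs Pat. Its het mean lay 1.14 SD of the het libraries from the midpoint of the paternal and maternal means, 72.0 against 69.9 CPM, as a fixed mixture of 2 kinds of X chromosome in the het libraries would give; this is a candidate explanation, and the crosses are not described in the labels. Broader X-linked differences were looked for among the 37 genes with an unadjusted p under 0.01 in Mat vs Pat. Of these 7, CG15572 itself among them, were X-linked, an odds ratio of 1.26 with an interval from 0.468 to 2.94. The 37 genes are below a share of 0.01 of the 12809 tested, the share expected with no change. The test therefore cannot decide, and that explanation stays open. An effect of the obese parent also stays open and was not tested apart from the direction of the cross.

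Lectin-28C was picked out because its change against het differed between the maternal and paternal groups, by 2.32 on the log2 scale. Reads running in from a neighbouring gene that itself rose were looked for. The largest change of the 2 tested genes within 10 kb was 0.2465 (SE 0.162) in Mat vs Het, for CG14535. This argues against a neighbour that rises along with lectin-28C. Both genes lie on the minus strand and lectin-28C on the plus strand. Reads can also run in without a change of the neighbour's own count, which this test cannot see, so that source stays open. TwdlE, which overlaps it, had at most 13 reads in a library and was not tested. A sequence difference carried by the mothers and an effect of maternal obesity stay open.

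Genes called against wildtype lay mostly on 2L, with odds ratios of 9.91, 13.7 and 12.8 against all other chromosomes in Het, Pat and Mat vs WT (4.35, 5.33 and 3.55 with the replicate block). Within 2L, genes up to 7.5 Mb from AkhR, a boundary chosen after the calls were seen, were called more often than those farther away. The lowest odds ratio over the 3 comparisons was 4.13 (interval from 1.64 to 13.3). AkhR starts at 6711286, so every gene farther than 7.5 Mb lies on the same side of it, at higher coordinates. This contrast therefore cannot tell distance from AkhR from position along the arm. The region within 2.5 Mb had a lower share than that at 2.5 to 7.5 Mb (2.07 against 3.18%, 2.23 against 3.00% and 1.59 against 1.91%, with overlapping 95% intervals). No decline with distance was thus seen inside 7.5 Mb, and linkage of sequence differences to the mutant allele stays open. Loss of reads from the mutant chromosome alone, where it differs from the reference genome, would lower nearly all called 2L genes. Of those called in Het vs WT 47.2% were higher (interval from 33.3 to 61.4%), which argues against such loss as the whole cause. Wildtype flies may differ from the reference too, and reads lost from their chromosome would raise genes in het flies. Loss on both sides was not tested and stays open, as does loss from the mutant chromosome for the genes that fell. It remains a hypothesis that these changes may follow the chromosome rather than AkhR function, since no library separates the allele from the arm around it.

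For counts of genes, the 10 splits of the 6 libraries are too few for a share under 0.05. The real splits gave 76, 67, 44, 1, 2 and 2 genes in Het vs WT, Pat vs WT, Mat vs WT, Pat vs Het, Mat vs Het and Mat vs Pat, and the highest of the other splits gave 0 in each, so that 1 split of 10 was as large in each. For lists the real splits gave 8, 13, 11, 3, 5 and 9, and the highest others 11, 11, 18, 10, 15 and 14. As many lists or more came from 5, 1, 4, 7, 10 and 9 of the 10 splits, real one included. Of the other splits, 3 part all replicate numbers as the real one does, and gave at most 7, 10, 10, 2, 13 and 12 lists and 0 genes.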

How the results depend on the processing

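Leaving out libraries in the list tests was chosen after the data were seen; the other alternatives were planned. Counts of genes in Het, Pat and Mat vs WT were 121, 104 and 89 with DESeq2, 183, 1.6e+02 (47 higher and 109 lower) and 27 with only the 6 libraries compared, 284, 206 and 227 with the replicate block, and 9, 8 and 12 with a 2-fold minimum, which also left 0 in Pat vs Het and 1 in Mat vs Het. The 2-fold minimum asks for a larger change by construction; for the others the cause was not tested. The block raised the genes shared by the 3 comparisons with wildtype from 32 to 104 and the lists in Mat vs Het from 5 to 10; it ended no call of a named gene or list, and brought past the threshold starch and sugar digestion in Het vs WT, Mat vs Het and Mat vs Pat, P450 genes in Het vs WT and Mat vs WT, muscle in Pat vs WT, storage proteins in Mat vs WT, beta-oxidation in Mat vs Het and Mat vs Pat, glutathione transferases, proteases and testis in Mat vs Het and mitochondrially encoded genes in Mat vs Pat. With an estimated correlation 0 lists passed in each of the 6 comparisons, as with fry in one direction. With fry in either direction 6 passed in Het vs WT (3 of them among the 8), 4 in Pat vs WT, 2 in Mat vs WT (1 of them among the 11) and 0 in Pat vs Het, Mat vs Het and Mat vs Pat. The cause was not tested.

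With 1 library left out, genes numbered 41 to 64 in Het vs WT, 33 to 45 in Pat vs WT, 27 to 116 in Mat vs WT, 1 to 2 in Pat vs Het, 2 to 3 in Mat vs Het and 2 in Mat vs Pat; lists numbered 8 to 10, 7 to 12, 8 to 12, 2 to 7, 2 to 12 and 2 to 11. Fewer samples enter these fits. Lists in Mat vs Het numbered 9 without het replicate 3, and 10 and 12 without maternal replicates 3 and 2; those in Pat vs Het numbered 7 without paternal replicate 1. AkhR, which passed in no comparison, ranged from -0.1061 to 0.0076 in Het vs WT, -0.1114 to -0.0266 in Pat vs WT, -0.0871 to 0.0042 in Mat vs WT, -0.0762 to 0.0392 in Pat vs Het, -0.0519 to 0.0669 in Mat vs Het and -0.0176 to 0.0711 in Mat vs Pat; it changed sign without het replicate 2 in Het vs WT (0.0076) and Mat vs Het (-0.0519), without maternal replicate 2 in Mat vs WT (0.0042), without het replicate 1, het replicate 3 or paternal replicate 2 in Pat vs Het (0.0392, 0.0113 and 0.0322), without maternal replicate 1 in Mat vs Het (-0.0235), and without paternal replicate 2 or maternal replicate 1 in Mat vs Pat (-0.0176 and -0.0144). Named genes that no longer passed numbered 3 in Het vs WT and 5 in Pat vs WT without scaling factors, 2 and 4 without robust fitting, and 1, 2 and 2 in Het, Pat and Mat vs WT with only the 6 libraries compared (CG14945; CG14945 and Ser8; CG31867 and CG5778). In Mat vs WT CG31867 did not pass with DESeq2 and CG43403 with limma-trend. AkhR in Het vs WT was -0.04 from the deposited FPKM. No scaling moved the median of all genes by more than 0.0204. The alternative pseudocounts were not run because the tables hold counts. In the simulated Het vs WT comparison 32% of genes changed by 1.2-fold were recovered, against 94% at 1.5-fold and 94% at 2-fold. These genes had a mean of at least 1 CPM, so recovery of lower ones was not measured, and depth was not varied.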

Other observations

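Several transcripts separate the sexes in Drosophila, and sex is not in the labels. The dosage compensation RNA roX1 stood at 379.2 to 388.5 CPM in the 3 wildtype libraries and at 305.1 to 356.5 CPM in the other 9. Its log2 change was -0.15, -0.15 and -0.20 in Het, Pat and Mat vs WT with adjusted p of 0.233, 0.251 and 0.117, and with the replicate block 0.0763, 0.0840 and 0.0255, so that only Mat vs WT passed, under the block alone. Whether this has one source with the lower accessory gland list was not tested, and that list did not hold in Het, Pat and Mat vs WT with an estimated correlation (adjusted p = 0.896, 0.658 and 0.603). The seminal fluid genes Acp26Aa and Acp36DE stood at 245 to 298 and 1477 to 1821 CPM over the 12 libraries. Mst84Da, of the testis and sperm list, stood at 219 to 288 CPM. The yolk protein genes Yp1, Yp2 and Yp3 stood at 1.85 to 3.93, 0.968 to 2.15 and 8.63 to 12.2 CPM. High male and low yolk protein transcripts in every library point to male flies in all 12, which the labels do not state.

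Some tissue lists lay on both sides of their mean within a group. In maternal flies the neuronal list had library medians of -0.29, 0.02 and 0.03 log2 against the mean of all libraries, and the accessory gland list had 0.08, 0.03 and -0.13. Mitochondrially encoded genes ranged from -0.31 to 0.32 over the 12 libraries.

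In the authors' deposited tables an exon of CG8837, on 2L from 3320518 to 3320647, had log2 ratios of -1.15 in Pat vs WT and -1.06 in Mat vs WT, while the log2 change of the gene as a whole in edgeR was 0.43 and 0.36, with adjusted p of 0.0227 and 0.0904, the latter being 0.0134 for CG8837 with the replicate block. Read on the scale of the gene scores, exons past an adjusted p of 0.05 in the authors' deposited tables numbered 4, 5, 8, 1 and 5 in Het, Pat and Mat vs WT, Pat vs Het and Mat vs Het, of which 3, 2, 4, 0 and 2 lay on 2L. An exon was listed at all for 99, 82, 99, 71 and 98 genes in these comparisons.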
